A study of Capra hircus with 9 samples.

How the data were processed

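Small RNA libraries were made from the submandibular gland of 9 healthy female Lubo goats, 3 at each of 3 ages: 1 month, 12 months and 24 months. Per the labels, each library came from a separate animal, the animals were kept under shared conditions, and total RNA was taken with TRIzol before Illumina sequencing. The libraries carry the replicate numbers 1, 2 and 3 at 1 month, 3, 4 and 5 at 12 months, and 2, 3 and 5 at 24 months, and those numbers are used below to name single libraries. FastQC and Bowtie are named without versions or roles, per the submitters' processing notes. The genome build and the miRNA database release are not given in the sources used here. The reference table of gene symbols was not used here, since mature miRNAs carry their own names.

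The deposited table by the authors holds unscaled read counts for 2189 mature miRNA entries, per the file headers. Of these, 418 carry goat names with the prefix chi-, 1292 carry names of other species ending in -x, -y or -z, and 479 are candidate entries without a family name. By seed match to goat miRNAs, the ending -x marks the 5p arm, with 94 of 640 entries sharing a goat 5p seed and 1 a 3p seed, and the ending -y marks the 3p arm, with 88 of 632 entries sharing a 3p seed and 0 a 5p seed. The entries are not independent: 218 of them share 62 sequences, so the same read can be counted under more than 1 name, and values for close family members are uncertain to that degree. Several entries with other names begin with the full sequence of a goat-named entry and run on by a few bases, and are longer forms of the same RNA. Library totals ran from 8288492 to 13277448 counts. At this depth the counting error of a list share is small against the spread between goats, and the Wilson 95% intervals given for single libraries cover counting error only.

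Entries were kept by the edgeR filter (minimum count 10, minimum total 15), which left 937 entries: 358 goat-named, 430 with other names and 149 candidate entries. These held at least 99.9% of the counts of every library. All 9 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM factors, robust quasi-likelihood F test, 6 residual degrees of freedom, biological coefficient of variation 0.534), and p-values were adjusted by Benjamini and Hochberg within each comparison at a threshold of 0.05. The comparisons were 12 months against 1 month, 24 months against 12 months, 24 months against 1 month, and any difference between the 3 ages. Levels are means ± standard deviation of TMM-scaled CPM (counts over the scaled library total) unless called unscaled, and errors in brackets after log2 fold changes are standard errors of the fit.

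The tests were checked on simulated data with 937 entries, 200 of them changed, in 10 repeats. For 12 months against 1 month, edgeR recovered 5.97% of 2-fold, 48.3% of 4-fold and 82.4% of 8-fold changes, with 3.14% of calls false. The same shares were 6.70%, 47.8% and 83.4% with 4.03% false for 24 months against 12 months, and 7.86%, 46.6% and 79.7% with 3.61% false for 24 months against 1 month. At 2-fold, DESeq2 1.42.0 recovered 14.6%, 14.8% and 16.0% in those comparisons with 7.35%, 8.70% and 6.73% false, and limma voom 3.58.1 recovered 7.47%, 8.33% and 9.15% with 4.12%, 4.48% and 3.75% false. In these simulations, which gave each miRNA the same spread at every age, most changes of 2-fold lay below what 3 goats per age could resolve.

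The miRNAs to name were fixed by a rule: among those past the threshold with non-overlapping ages and a mean of at least 10 CPM in 1 age, the 10 known miRNAs with the largest rise and the 10 with the largest fall. Added to these were the 10 most abundant miRNAs and up to 4 most abundant members of each list, and where fewer than 5 known miRNAs qualified, the 10 with the smallest p, said not to have passed. Names outside the rule are said to be chosen after their values were seen. Candidate entries without a family name are counted but not named here.

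The lists, the comparisons, the test, the filter, the naming rule and 25 of the alternative settings were fixed before the data were examined. The 19 lists, each covering both arms, were let-7 with miR-98, known for rising with differentiation; the miR-17-92 cluster and its paralogs, tied to proliferation; the imprinted DLK1-DIO3 region; an imprinted and X-linked growth network; epithelial miRNAs (miR-200, 141, 429, 203, 205, 183, 96 and 182); exocrine and endocrine gland miRNAs (miR-148, 375, 7, 216 and 217); muscle; leukocyte (miR-142, 150, 155, 223, 146 and 342); red cell (miR-144, 451 and 486); endothelial (miR-126); mesenchymal (miR-143, 145, 199 and 214); neural (miR-9, 124, 128, 129, 137 and 219); hepatic (miR-122); miR-29 and miR-21, tied to matrix; miR-34 with its miR-449 relatives; miR-15/16, brakes of the cell cycle; miR-30; miR-181; and Hox (miR-10a, 10b, 196 and 615). The miR-181 and epithelial lists name lettered members, so miR-181-x and miR-200-x lie outside both. Thymocyte, mature lymphocyte and myeloid, and fish-named lists were added after levels had been seen.

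Lists with at least 3 tested members were tested with camera at a correlation of 0.01, and again with an estimated correlation and with fry. In 10 simulated runs with 1 list raised 2-fold for 12 months against 1 month, camera recovered the list in 10 and passed 2 of 180 others, and fry recovered it in 8 and passed 0 of 180 others. Camera asks whether a list moved more than the other miRNAs and takes its members as nearly independent, which members of 1 cluster are not. The simulated entries were drawn independently as well, so these runs do not show how often camera passes lists of correlated members. In the data the estimated correlation for 12 months against 1 month was 0.857 for miR-17-92 and 0.431 for epithelial. Shares of all counts per list and library measures were compared by exact two-sided permutation tests over the 10 splits of 6 libraries, whose smallest p is 0.1, and adjusted over the lists or measures.

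Alternatives were the size factors of DESeq2 in edgeR, library size alone, upper quartile, no filter, a mean of at least 10 CPM, DESeq2 and limma voom in place of edgeR, known miRNAs only, a 2-fold minimum, only the libraries of the ages compared, the replicate number as a block, each library left out in turn, the more abundant arm only for lists, and other denominators for shares. After the data had been seen, 13 more were added: a split of the libraries by a first-base ratio as a covariate and within its low side, entries of the same sequence collapsed, goat-named entries only, 1-month library 2 and 12-month library 4 left out together, and TMM with each of the other 8 libraries as reference. The first-base ratio is the count of miR-26-x, which differs from chi-miR-26a-5p in its first base, as a percent of chi-miR-26a-5p. The estimated correlation was also run with each library left out. The pseudocount alternatives were not run, since the table holds counts. Overlap of the comparisons that share the 1-month libraries was set against 50 simulations with shared controls and no age effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw reads were not analysed here.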

Results

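The submandibular gland of 3 goats at 1 month, 3 at 12 months and 3 at 24 months gave 9 small RNA libraries with counts for 2189 mature miRNA entries. The 10 most abundant miRNAs were chi-miR-26a-5p, chi-miR-148a-3p, chi-miR-143-3p, chi-miR-99a-5p, chi-miR-27b-3p, chi-let-7a-5p, chi-miR-125b-5p, chi-miR-191-5p, chi-miR-200a and miR-181-x. chi-miR-26a-5p led at 1 month with 121181 ± 4022 unscaled CPM, and stood at 109675 ± 18294 and 101883 ± 13666 at 12 and 24 months. chi-miR-148a-3p, a miRNA rich in secretory glands, led at 12 and 24 months with 130783 ± 10782 and 138008 ± 2501 unscaled CPM, against 42238 ± 34436 at 1 month. miR-181-x, of a family known in lymphocyte development, stood at 65765 ± 56506 unscaled CPM at 1 month and at 4842 ± 449.2 and 3922.5 ± 149.7 later. The 10 most abundant miRNAs of each library took 52.9 ± 6.19%, 53.2 ± 2.52% and 53.8 ± 1.21% of its counts at 1, 12 and 24 months (exact two-sided p = 1, 0.7 and 1 for 12 against 1, 24 against 12 and 24 against 1 month).

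Libraries held 10339013 to 13277448 counts at 1 month, 8288492 to 12064729 at 12 months and 9308751 to 10810647 at 24 months (exact two-sided p = 0.3, 0.9 and 0.2), and 1465 ± 21.2, 1271 ± 85.5 and 1210.0 ± 78.8 entries were detected (exact p = 0.1, 0.5 and 0.1, adjusted p = 0.45, 0.9 and 0.45, where 0.1 is the smallest p for 3 against 3). Within-age correlations of log2 CPM ran from 0.969 to 0.983 at 12 months and from 0.974 to 0.983 at 24 months. At 1 month they ran from 0.915 to 0.987, and library 2 stood apart. Only 66.6% of its counts fell on goat-named entries, against 79.7% to 83.6% in the other 8 libraries, and its leukocyte list took 12.6% of counts (95% interval 12.57 to 12.61%), against 3.70% and 5.76% in 1-month libraries 1 and 3. Its epithelial and gland lists took 0.845% and 1.37%, against 4.96% and 8.44% in library 1 and 3.41% and 6.42% in library 3. Many values at 1 month therefore carry a wide spread, and for many of the miRNAs described below results without library 2 are given as well.

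Between 1 and 12 months the leukocyte and miR-17-92 lists fell and the epithelial and the miR-29 and miR-21 lists rose by camera, while none of these list calls held with an estimated correlation. The leukocyte list fell by 3.56 at its median (log2), with 12 of 15 tested members lower and 0 higher, and 14 lower when adjusted over the list alone (adjusted p = 0.364 with an estimated correlation). Its most abundant member, miR-142-x, a marker of all blood-forming cells, went from 51099 ± 45431 to 1193 ± 32.0 CPM. The miR-17-92 cluster and its paralogs, which promote proliferation, fell by 2.54 at the median, with 24 of 26 lower and 0 higher, and 25 lower when adjusted over the list alone (adjusted p = 0.489 with an estimated correlation). The epithelial list, whose miR-200 and miR-141 members hold cells in an epithelial state, rose by 1.61 at the median, with 4 of 19 higher and 12 higher when adjusted over the list alone (adjusted p = 0.489 with an estimated correlation). The 4 were chi-miR-141, its longer form miR-141-y, the other arm miR-141-x, and chi-miR-200c. The miR-29 and miR-21 list rose by 1.04 at the median, with 4 of 9 higher, the same number when adjusted over the list alone, and all 4 were arms of miR-29, which restrains collagen synthesis (adjusted p = 0.364 with an estimated correlation). chi-miR-21-5p did not pass, and the share of this list in all counts was 1.60% at 1 month and 1.37% at 12 months.

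Among rises, chi-miR-29b-3p went from 59.2 ± 12.2 to 554 ± 83.5 CPM (log2 3.23, SE 0.35, adjusted p = 0.0011, higher in 3 of 3 goats). The other arm, chi-miR-29b-5p, rose by 2.83 (0.39, adjusted p = 0.00151), miR-29-y by 2.51 (0.30, adjusted p = 0.0011) and chi-miR-29a-3p by 1.72 (0.31, adjusted p = 0.00473, and 0.0512 without 12-month 5). miR-29-y begins with the full sequence of chi-miR-29a-3p and runs on by 2 bases, so it is a longer form of the same RNA and no separate evidence, and the same holds for miR-141-y beside chi-miR-141. chi-miR-141, which keeps epithelial junctions in place, went from 4328 ± 2537 to 25409 ± 1962 CPM (2.55, 0.47, adjusted p = 0.00497), with miR-141-x at 2.75 (0.47, adjusted p = 0.00403) and miR-141-y at 2.46 (0.58, adjusted p = 0.0149, lost at 0.0635 and 0.0516 without 12-month 4 or 5). miR-200-x rose by 2.77 (0.66, adjusted p = 0.0155, lost at 0.0619 and 0.0811 without 12-month 3 or 5), and chi-miR-200c by 2.01 (0.59, adjusted p = 0.0361). The call of chi-miR-200c was lost at 0.0725 to 0.171 on leaving out 1-month 3 or any 12-month or 24-month library. miR-375-y, a regulator of secretion in endocrine and exocrine cells, went from 8371 ± 224 to 23096 ± 5638 CPM (1.46, 0.30, adjusted p = 0.00779). It did not pass without 12-month 3 (0.0661), 12-month 5 (0.148), 24-month 2 (0.0532) or 24-month 3 (0.051).

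miR-6516-y and miR-6516-x, of little known function, rose by 2.81 (0.57, adjusted p = 0.00751) and 2.59 (0.46, adjusted p = 0.00476). miR-8-y carries the name of the insect relative of the miR-200 family and had the largest rise by the naming rule, from 2.87 ± 1.48 to 49.2 ± 62.5 CPM (4.10, 1.16, adjusted p = 0.0329). That mean rested on 12-month 4, at 121 CPM against 12.0 and 14.3 in 12-month 3 and 5, and the rise was 2.21 with an adjusted p of 0.123 without it. It also did not pass without 1-month 1, 2 or 3 (0.0901, 0.0864 and 0.0982). chi-miR-499-5p, a miRNA of slow muscle fibres, went from 32.0 ± 10.6 to 77.9 ± 11.7 CPM (1.28, 0.39, adjusted p = 0.0421), a call lost at 0.0943 to 0.281 on leaving out 1-month 3 or any 12-month or 24-month library.

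Among falls, miR-142-x and miR-142-y fell by 5.42 (0.63, adjusted p = 0.0011) and by 5.62 (0.77, adjusted p = 0.00151), with −4.42 and −4.17 without 1-month 2. chi-miR-128-3p, known in neurons and in early lymphocytes, went from 12883 ± 15274 to 398 ± 86.4 CPM (−5.02, 0.85, adjusted p = 0.00385), and −3.38 without 1-month 2. miR-128-y, a longer form of chi-miR-128-3p, had a value of −7.52 (1.06, adjusted p = 0.00154), and −5.49 without 1-month 2. Within the proliferation group, chi-miR-20b fell from 78.5 ± 59.8 to 2.51 ± 0.391 CPM (−4.96, 0.65, adjusted p = 0.00136, −4.20 without 1-month 2). The abundant members chi-miR-25-3p, chi-miR-92b and chi-miR-92a-3p fell by 2.42 (0.53, adjusted p = 0.0115), 2.24 (0.51, adjusted p = 0.0137) and 2.23 (0.51, adjusted p = 0.0138). Without 1-month 2 they stood at −1.55, −1.42 and −1.41, and without 12-month 4 their adjusted p was 0.0559, 0.0635 and 0.0635. chi-miR-92b and chi-miR-92a-3p are listed with the same sequence and with unequal counts, at 9368 and 10255 CPM at 1 month, so they are no separate evidence. chi-miR-301b went from 18.4 ± 20.4 to 0.303 ± 0.321 CPM (−5.83, 1.08, adjusted p = 0.00497), with −4.38 without 1-month 2. Without 12-month 4 it held 698 counts at 1 month against 3 at 12 months, a ratio of 134 (95% counting interval 45.8 to 653). miR-3548-y, of little known function, and miR-3969-x, which shares a run of 19 bases with miR-142-x, stood at −6.81 (0.84, adjusted p = 0.00113) and −5.38 (0.80, adjusted p = 0.00196), and at −5.61 and −4.23 without 1-month 2.

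Myeloid chi-miR-223-3p and miR-223-y fell by 4.88 (1.43, adjusted p = 0.0369) and by 4.92 (1.21, adjusted p = 0.018). Both rested on 1-month 3, at 625 CPM of chi-miR-223-3p against 22.0 and 34.1 in 1-month 1 and 2, and stood at −1.85 (adjusted p = 0.185) and −2.36 (adjusted p = 0.129) without it. As miR-223-y is a longer form of chi-miR-223-3p, this is 1 result. miR-223-y did not pass without 12-month 4 (0.0666) or 5 (0.05001), and chi-miR-223-3p did not pass without 12-month 3, 4 or 5 or 24-month 3 (0.0504 to 0.0842). miR-181-x and chi-miR-181b-5p, which tune receptor signals in lymphocytes, fell by 3.69 (0.63, adjusted p = 0.00397) and 3.33 (0.55, adjusted p = 0.00332), with −2.49 and −2.43 without 1-month 2. Of the cell cycle brakes, chi-miR-15b-5p and chi-miR-16b-5p fell by 3.91 (0.62, adjusted p = 0.0025) and 2.81 (0.52, adjusted p = 0.00497), with −2.82 and −1.95 without 1-month 2. chi-miR-342-3p fell by 1.55 (0.36, adjusted p = 0.0142), and had an adjusted p of 0.0739 without 12-month 4. chi-miR-146a (−0.53, adjusted p = 0.294), chi-miR-19b-3p (−1.11, adjusted p = 0.138), chi-miR-21-5p (−0.50, adjusted p = 0.331) and chi-miR-16a-5p (−1.54, adjusted p = 0.0631) did not pass. The last passed without 1-month 1 or 3 or 24-month 2 or 3 (0.0357 to 0.0475).

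Some rises that did not pass over all libraries passed without 1-month 2, at smaller log2 fold changes. chi-miR-148a-3p stood at 35621 ± 28511 CPM at 1 month and 134928 ± 11257 at 12 months (1.92, adjusted p = 0.0626), and passed without 1-month 2 (1.38, adjusted p = 0.00123) or 1-month 1 (adjusted p = 0.0441). Epithelial chi-miR-200a (1.89, adjusted p = 0.0695) and chi-miR-200b (1.98, adjusted p = 0.0748) also passed without it, at 1.33 (adjusted p = 0.00123) and 1.42 (adjusted p = 0.00314), and chi-miR-200b passed without 1-month 1 (2.67, adjusted p = 0.0466). chi-miR-30a-5p (1.57, adjusted p = 0.0866) and chi-let-7b-5p (1.05, adjusted p = 0.0951) passed at 1.04 (adjusted p = 0.00915) and 0.64 (adjusted p = 0.0372).

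In total, edgeR called 180 of 937 miRNAs between 1 and 12 months, 56 higher and 124 lower: 76 goat-named, 74 with other names and 30 candidate entries without a family name. Of these, 179 changed at least 2-fold and 179 did not overlap between ages. Over all tested, 454 (48.5%) did not overlap, where chance gives 10%. The balance of directions depended on the setting: library size alone shifted the median of all miRNAs from −0.02 to −0.20 and gave 26 higher and 155 lower (14.4% higher, against 31.1%), limma voom gave 98 and 129 (43.2%), and only the libraries of both ages gave 21 and 134 (13.5%). Without 1-month 2 the counts were 84 higher and 134 lower, with 150 of the 180 kept, and without 12-month 4 only 83 were called.

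By camera, 4 of 19 lists passed between 1 and 12 months: miR-17-92 (adjusted p = 6.6e-12), leukocyte (1.0e-08), epithelial (5.3e-06) and miR-29 and miR-21 (0.0124). None of the 4 passed with an estimated correlation (adjusted p = 0.489, 0.364, 0.489 and 0.364 with an estimated correlation). Of the 10 splits of these 6 libraries, the real one included, 10 passed at least 4 lists by camera. The number of lists passed therefore does not set the real ages apart from mixed ones. fry passed leukocyte (0.00936), epithelial (0.0239), miR-29 and miR-21 (0.00936) and miR-30 (0.00936), and left miR-17-92 at 0.0506. Without 1-month 2 the medians were −2.84 for leukocyte with 11 of 15 lower, −1.54 for miR-17-92 with 22 of 26 lower, 1.14 for epithelial with 11 of 19 higher and 1.46 for miR-29 and miR-21 with 4 of 9 higher. Without 1-month 1 the miR-29 and miR-21 list had an adjusted p of 0.0506. The directions of these 4 lists held under TMM, library size, DESeq2 size factors and upper quartile.

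The 15 other lists did not pass camera between 1 and 12 months. miR-15/16 had a median of −1.17 (6 of 16 lower, and 7 lower and 1 higher when adjusted over the list alone, adjusted p = 0.0678), miR-181 of −1.66 (1 of 4 lower, 3 adjusted over the list alone, adjusted p = 0.0678) and neural of −0.98 (3 of 13 lower, 4 adjusted over the list alone, adjusted p = 0.0678). The 3 neural calls were chi-miR-128-3p, miR-128-y and chi-miR-129-5p, the last picked after its values were seen (−3.33, adjusted p = 0.0138). miR-30 stood at 0.87 (adjusted p = 0.0678), DLK1-DIO3 at 0.23 with 0 of 84 called (adjusted p = 0.0678), growth network at 0.65 with 0 of 20 (0.261), Hox at −0.99 with 0 of 5 (0.261), muscle at 1.36 with 2 of 9 higher (0.189), mesenchymal at 0.44 (0.261), endothelial at 0.41 (0.416) and red cell at −0.55 (0.5999). Picked after their values were seen, the single calls in these lists were chi-miR-30b-3p (1.33, adjusted p = 0.0272) and miR-145-y (1.91, adjusted p = 0.0256), and chi-miR-499-3p was the other muscle call (1.42, adjusted p = 0.0369). let-7 had a median of −0.03 (0.974), with chi-let-7b-3p higher (1.99, adjusted p = 0.0171) and chi-let-7i-5p lower (−1.26, adjusted p = 0.02), both picked after the fact. The gland list had a median of −0.16, a mean of 0.10 and a test direction of up (0.729), with miR-375-y higher and chi-miR-7-5p lower (−1.41, adjusted p = 0.0305, picked after the fact), and 3 higher and 2 lower when adjusted over the list alone. The hepatic list had a median of 0.24, a mean of −1.22 and a test direction of down (0.932), and the miR-34 family stood at 0.15 (0.932). With library size alone the medians of DLK1-DIO3, hepatic and the miR-34 family turned to −0.03, −0.02 and −0.05, and with the upper quartile that of let-7 turned to 0.10.

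Calls of these lists between 1 and 12 months turned on single libraries, and none of those gained on leaving out a library passed with an estimated correlation. DLK1-DIO3 passed upward without 1-month 1 (0.42 at 0.0142, adjusted p = 0.767 with an estimated correlation), 1-month 3 (0.51 at 0.00231, 0.788) or 12-month 4 (0.33 at 0.00954, 0.805). Without 1-month 2 its median was −0.08 with 4 members lower and 0 higher, and it was also negative without 12-month 3 or 5 or any 24-month library (−0.21 to −0.14). With the first-base split as a covariate and all libraries it passed upward (0.42 at 0.0388, with 4 members higher and 0 lower). Mesenchymal passed upward without 1-month 3 (0.76 at 0.0413, 0.788), and without 1-month 2 its median was −0.09 with 3 members higher and 4 lower. It was also negative without 12-month 3 (−0.32) or 5 (−0.16). Muscle passed without 12-month 3 (1.21 at 0.0479, 0.631) or 5 (1.20 at 0.0172, 0.579), which only gives more weight to 12-month 4, where the list took 0.246% of counts against 0.0269% and 0.0230%. Without 12-month 4 the muscle median was −0.63. Neural passed without 1-month 2 (−0.62 at 0.0463, 0.386), 1-month 3 (−1.33 at 0.0473, 0.537) or 12-month 5 (−1.53 at 0.0400, 0.501), and miR-30 without 1-month 2 (0.66 at 0.0212, 0.606) or 12-month 4 (0.86 at 0.0384, 0.556). miR-15/16 (−1.54 at 0.0247, 0.512) and miR-181 (−2.03 at 0.0144, 0.512) passed without 1-month 3, and without 1-month 2 their medians shrank to −0.26 (0.0823) and −0.62 (0.178).

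As shares of all counts, the leukocyte list took 7.35 ± 4.65% at 1 month, 0.612 ± 0.0720% at 12 months and 0.515 ± 0.0790% at 24 months, and miR-17-92 took 3.82 ± 2.46%, 0.765 ± 0.0654% and 0.684 ± 0.00988%. Gland miRNAs took 5.41 ± 3.64%, 15.6 ± 1.35% and 17.1 ± 0.513%, and epithelial miRNAs 3.07 ± 2.08%, 9.23 ± 0.496% and 9.57 ± 0.537%. Against 1 month each of these 4 lists had non-overlapping shares at both later ages, with an exact two-sided p of 0.1, the smallest for 3 against 3. The same held for miR-15/16 (2.66, 0.722 and 0.669%), neural (1.54, 0.0477 and 0.0360%) and miR-181 (0.357, 0.0629 and 0.0661%). Few miRNAs carried most of the neural and gland shares. In 1-month 2 the neural list took 3.48%, with chi-miR-128-3p at 28849 unscaled CPM and its longer form miR-128-y at 5871. In 1-month 1 the gland list took 8.44%, with chi-miR-148a-3p at 71277 and miR-375-y at 10163. The gland list itself did not pass camera between 1 and 12 months (median −0.16, adjusted p = 0.729). In all, 7 of 19 lists had non-overlapping shares between 1 and 12 months (36.8%, where chance gives 10%), 3 of 19 between 12 and 24 months (15.8%) and 9 of 19 between 1 and 24 months (47.4%). The smallest adjusted exact p was 0.271, 0.633 and 0.211.

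**Figure D1:**
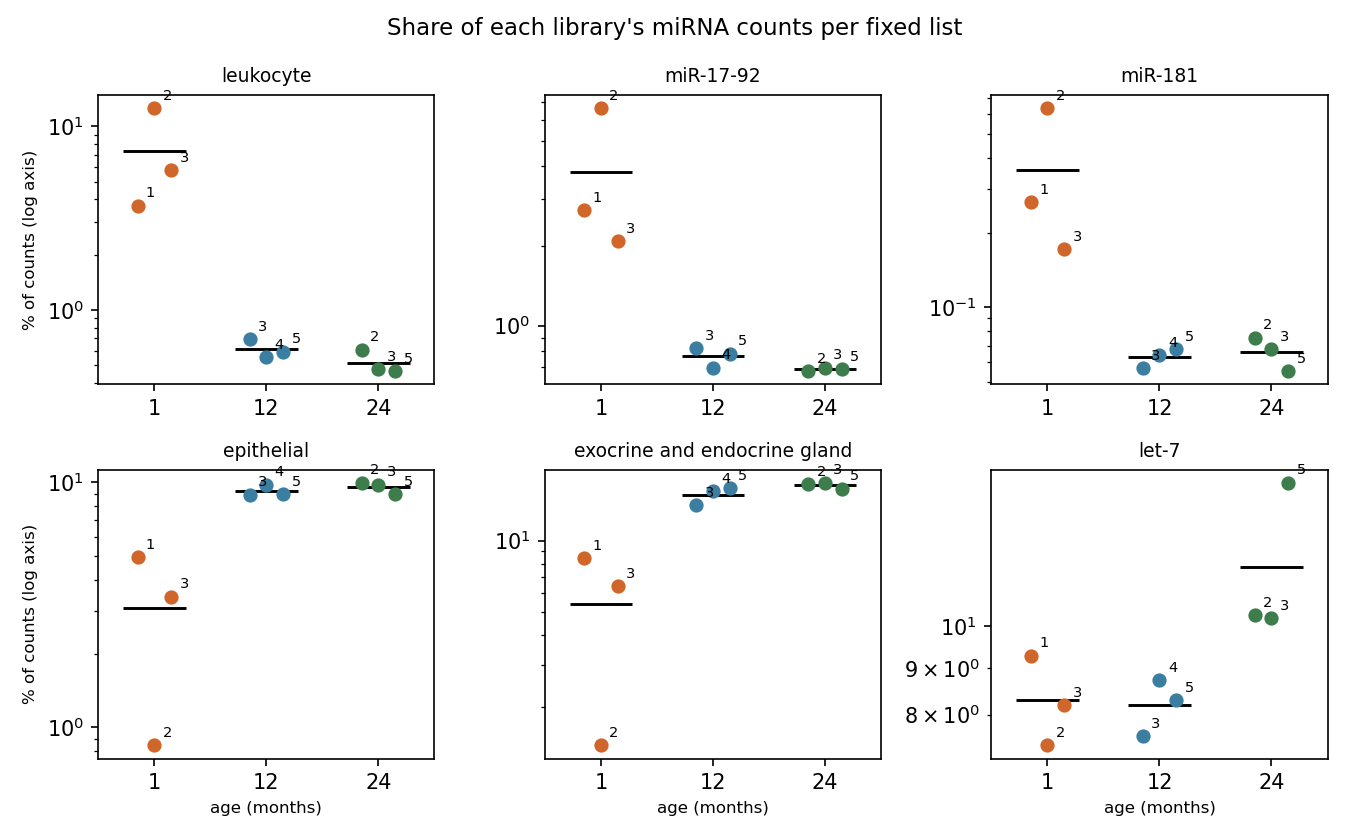
Share of all counts (percent, log axis) taken by 6 miRNA lists at 1, 12 and 24 months. Points are single goats marked with their replicate number and lines are age means, with the leukocyte list at 12.6% in 1-month 2 and at 0.515% on average at 24 months.

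Between 12 and 24 months no miRNA passed the test. The lists called against 1 month at both ages had medians of −0.17 (leukocyte), −0.02 (miR-17-92), 0.09 (epithelial) and 0.02 (miR-29 and miR-21), while hepatic, muscle and red cell stood at 3.35, −1.28 and −0.94. chi-let-7a-5p, which marks differentiated cells, stood at 33604 ± 2115 CPM at 12 months and 56649 ± 20106 at 24 months (0.75, SE 0.34), and chi-let-7b-5p at 16789 ± 254 and 26406 ± 2793 (0.65, 0.43). The let-7 list was the largest share to part these ages, at 8.20 ± 0.580% against 11.6 ± 2.36% (exact p = 0.1), with 24-month 5 at 14.3% (95% interval 14.31 to 14.35%). miR-142-x stood at 1193 and 1055 CPM (−0.18, 0.52), chi-miR-141 at 25409 and 27953 (0.14, 0.44), chi-miR-29b-3p at 554 and 678 (0.29, 0.32), miR-375-y at 23096 and 31910.4 (0.47, 0.29) and chi-miR-148a-3p at a log2 value of 0.14.

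With edgeR 0 of 937 miRNAs were called between 12 and 24 months, with 40 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. DESeq2 called 0 with 42 unadjusted and limma voom 0 with 13 unadjusted. Ages did not overlap for 92 miRNAs (9.82%, where chance gives 10%). The median size of a log2 fold change was 0.32, and the median 95% interval, before adjustment, reached 1.22 to either side. In the simulated data edgeR recovered 6.70% of 2-fold and 47.8% of 4-fold changes between these ages. Under that simulated spread most changes of 2-fold and many of 4-fold would have gone unseen. The simulations gave each miRNA the same spread at every age. In the data the 1-month libraries varied more, with within-age correlations from 0.915, against 0.969 at 12 months and 0.974 at 24 months. The recovery rates may therefore not hold for these ages. Leaving out 12-month 5 gave 2 calls, both candidate entries without a family name.

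The miRNAs with the smallest p between 12 and 24 months, none of which passed (adjusted p = 0.998 for each), included several led by single libraries. Muscle chi-miR-206 stood at 282 ± 471 and 7.62 ± 2.98 CPM (−5.21, 1.53), with 826 CPM in 12-month 4 against 10.6 and 10.1 in 12-month 3 and 5. miR-462-x and miR-7132-x, with names from fish and their highest 12-month levels in 12-month 4 (67.6 and 39.3 CPM), stood at 30.3 ± 33.2 and 2.11 ± 1.31 (−3.83, 1.14) and at 15.9 ± 20.3 and 1.09 ± 0.432 (−3.85, 1.27). Liver chi-miR-122 stood at 74.0 ± 47.5 and 562 ± 771 (2.92, 1.20), with 1443.6 CPM in 24-month 3 against 226 and 16.5 in 24-month 2 and 5. miR-1260-x (761 ± 42.0 and 321 ± 169, −1.25, 0.40) and miR-365-y (10.7 ± 2.76 and 23.9 ± 5.49, 1.16, 0.41) did not overlap between these ages and were led by no single library. The others were red cell chi-miR-144-3p (402 ± 308 and 150.5 ± 29.4, −1.42, 0.59), chi-let-7a-3p (121 ± 32.6 and 259 ± 128, 1.10, 0.48), miR-10955-y (559 ± 193 and 278 ± 128, −1.01, 0.44) and chi-let-7a-5p.

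By camera, 3 lists passed between 12 and 24 months without a single called member: hepatic (median 3.35, adjusted p = 0.00289, 3 of 3 higher when adjusted over the list alone), red cell (−0.94, adjusted p = 0.0143) and let-7 (0.24, adjusted p = 0.0213). None passed with an estimated correlation (adjusted p = 0.468, 0.726 and 0.442 with an estimated correlation) or by fry (0.817, 0.897 and 0.558). At least 3 lists also passed camera in 6 of the 10 splits of these 6 libraries, the real one included. The hepatic call rested on 24-month 3, with a median of 0.90 and an adjusted p of 0.387 without it, and was also lost without 12-month 3 (0.0617) or 24-month 2 (0.0673). Its member miR-122-y was at 0 in every 12-month library against 55 counts at 24 months. Pooled over each age this was at least 17.9-fold higher at a floor of 3 counts over the group, and the list's median was 3.35 with that bound too. The bound does not hold for each goat, since miR-122-y stood at 1.48, 4.19 and 0 unscaled CPM in 24-month 2, 3 and 5. The red cell call was lost without 12-month 3 (−0.51, 0.0690), 12-month 4 (−0.30, 0.646) or 24-month 2 (−0.60, 0.217). The let-7 call was lost without 12-month 3 (0.42, 0.0617), 12-month 4 (0.22, 0.0888) or 24-month 5 (0.35, 0.176).

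The other 16 lists did not pass between 12 and 24 months, with 0 members called in each. Medians and adjusted p were 0.22 and 0.152 for gland, −0.19 and 0.152 for DLK1-DIO3, −1.28 and 0.157 for muscle, −0.14 and 0.225 for Hox, 0.09 and 0.352 for epithelial, −0.25 and 0.352 for mesenchymal, and 0.10 and 0.352 for miR-30. They were −0.33 and 0.377 for the miR-34 family, −0.13 and 0.460 for neural, 0.12 and 0.516 for miR-181, −0.17 and 0.874 for leukocyte, −0.15 and 0.874 for endothelial and 0.01 and 0.874 for miR-15/16. The miR-17-92 list had a median of −0.02 with a test direction of up (0.874), miR-29 and miR-21 a median of 0.02 and a mean of −0.18 with a direction of up (0.874), and growth network a median of 0.11 and a mean of −0.30 (0.9745). Library size alone turned the medians of miR-29 and miR-21 and of miR-15/16 to −0.05, and DESeq2 size factors turned that of miR-17-92 to 0.04. With the first-base split as a covariate the epithelial list passed (0.32 at 0.0463). Without 12-month 3 or 5 the muscle list passed (−1.42 at 0.0018 and −1.47 at 0.000199, adjusted p = 0.801 and 0.535 with an estimated correlation). That fall is carried by 12-month 4, with 0.246% of counts on this list against 0.0269% and 0.0230% in 12-month 3 and 5, and without 12-month 4 the median was 0.41 (0.449). DLK1-DIO3 and Hox passed without 12-month 4 (−0.26 at 0.0115 and −0.34 at 0.0355, adjusted p = 0.884 and 0.585 with an estimated correlation). Mesenchymal (7.86 ± 1.08 and 6.39 ± 0.198%) and endothelial shares (0.862 ± 0.0792 and 0.724 ± 0.0281%) did not overlap between these ages (exact p = 0.1 for both, adjusted 0.633).

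Between 1 and 24 months the leukocyte and miR-17-92 lists fell and the epithelial, miR-29 and miR-21, and miR-30 lists rose by camera, while none of these list calls held with an estimated correlation. The leukocyte list fell by 3.35 at its median with 14 of 15 lower and 0 higher, and all 15 lower when adjusted over the list alone (adjusted p = 0.365 with an estimated correlation). The miR-17-92 list fell by 2.56 with 24 of 26 lower and 25 adjusted over the list alone (0.550 in the same test). The epithelial list rose by 1.66 with 7 of 19 higher and 14 higher adjusted over the list alone (0.462), and the miR-29 and miR-21 list rose by 1.53 with 4 of 9 higher by both counts (0.365). The miR-30 list, linked to differentiated epithelium, rose by 0.97 with 2 of 11 higher, and 1 when adjusted over the list alone (0.365). Without 1-month 2 the medians were −2.68 for leukocyte with 11 of 15 lower, −1.66 for miR-17-92 with 21 of 26 lower, 1.18 for epithelial with 12 of 19 higher, 1.17 for miR-29 and miR-21 with 4 of 9 higher and 0.73 for miR-30 with 5 of 11 higher. miR-30 had not passed by 12 months, and whether the ages differ in this was not tested beyond the comparison of 24 with 12 months above. chi-miR-148a-3p rose from 35621 ± 28511 to 148375 ± 3432 CPM.

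**Figure D2:**
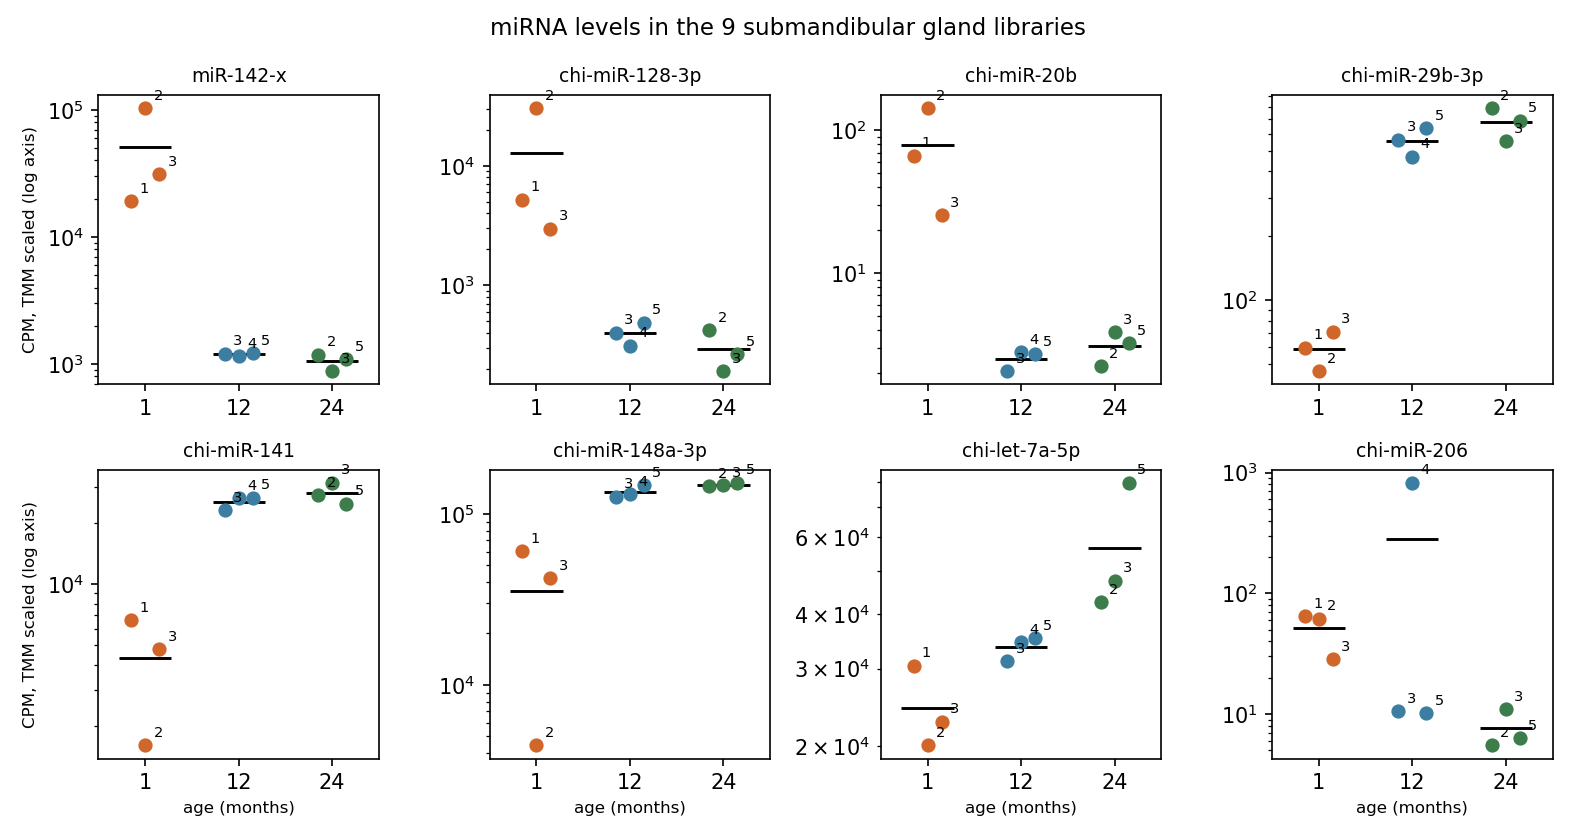
Levels of 8 miRNAs (TMM-scaled CPM, log axis) at 1, 12 and 24 months. Points are single goats, lines are age means, and miR-142-x runs from 51099 CPM at 1 month to 1055 at 24 months.

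Among rises, chi-miR-29b-3p reached 678 ± 118 CPM (3.52, SE 0.36, adjusted p = 0.000553), miR-29-y 1455 ± 105 (2.95, 0.31, adjusted p = 0.000553), chi-miR-29b-5p 25.0 ± 4.64 (2.84, 0.39, adjusted p = 0.00146) and chi-miR-29a-3p 4632 ± 674 (1.80, 0.31, adjusted p = 0.00341). The epithelial chi-miR-141 reached 27953 ± 3392 (2.69, 0.47, adjusted p = 0.00367), miR-141-y 1979.8 ± 721 (2.89, 0.59, adjusted p = 0.00772), miR-200-x 1699 ± 151 (2.86, 0.66, adjusted p = 0.0121, and 0.0525 without 24-month 3) and chi-miR-200c 8449 ± 2468 (2.07, 0.59, adjusted p = 0.0275, lost at 0.0614 to 0.127 without 1-month 3, 12-month 3 or 5, or any 24-month library). The gland miRNA miR-375-y reached 31910.4 ± 2378 (1.93, 0.30, adjusted p = 0.0022). chi-miR-148a-3p rose by 2.06 (0.68, adjusted p = 0.0454), with 1.51 at an adjusted p of 0.000754 without 1-month 2, and 0.0592 to 0.145 without 1-month 3 or any 12-month or 24-month library. chi-miR-1224, known from brain and stressed tissue, went from 0.943 ± 0.544 to 14.8 ± 5.55 CPM (3.96, 0.61, adjusted p = 0.00216), and miR-6516-y and miR-6516-x reached 37.0 ± 13.2 (3.26, 0.58, adjusted p = 0.0039) and 34.9 ± 18.02 (2.92, 0.47, adjusted p = 0.00249). miR-8-y reached 115 ± 90.0 (5.33, 1.22, adjusted p = 0.0124). miR-236-y, which carries the name of the worm relative of miR-200, rose by 4.72 (1.29, adjusted p = 0.0245), and without 1-month 1 it held 2 counts at 1 month against 269 at 24 months, a ratio of 112 (95% counting interval 30.7 to 930.0). It did not pass without 1-month 2 (4.36, 0.0847), 24-month 3 (0.0722) or 24-month 5 (3.93, 0.0813).

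chi-let-7b-5p rose from 8091 ± 4518 to 26406 ± 2793 CPM (1.71, 0.44, adjusted p = 0.0199), a call lost at 0.0603 to 0.104 without 12-month 3 or 5 or any 24-month library. chi-let-7a-5p rose from 24394 ± 5414 to 56649 ± 20106 (1.22, 0.34, adjusted p = 0.026), and stood at 0.72 (adjusted p = 0.2) without 24-month 5, and at 0.0622 to 0.0938 without 1-month 3, 12-month 3 or 5, or 24-month 2 or 3. chi-miR-499-5p rose by 1.61 (0.40, adjusted p = 0.0161), and had an adjusted p of 0.0779 and 0.0937 without 24-month 2 or 3. Of the endothelial list, miR-126-x rose by 1.20 (0.40, adjusted p = 0.0487, at 0.0534 to 0.232 without any 1 of the 9 libraries). It shares a run of 21 bases with the abundant chi-miR-126-5p, at 3257, 1824 and 4425 CPM at 1 month and 2804, 3368 and 3369 at 24 months. The other 3 members did not pass, and the share of the list was 0.968% at 1 month and 0.724% at 24 months. chi-miR-30b-5p rose by 0.97 (0.32, adjusted p = 0.0461, at 0.0747 to 0.217 without 1-month 3 or any 12-month or 24-month library). Epithelial chi-miR-200a (2.03, adjusted p = 0.0506) and chi-miR-200b (2.02, adjusted p = 0.0606) did not pass, and did without 1-month 1 (0.0386 and 0.0393) or 1-month 2 (0.000754 and 0.00266). chi-miR-30a-5p (1.72, adjusted p = 0.0559) also passed without 1-month 1 (0.0430) or 1-month 2 (0.00406).

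Among falls, miR-142-x reached 1055 ± 155 CPM (−5.60, 0.64, adjusted p = 0.000678), miR-142-y 84.8 ± 14.6 (−5.46, 0.77, adjusted p = 0.00146), chi-miR-128-3p 290.4 ± 116 (−5.47, 0.86, adjusted p = 0.00229), miR-128-y 12.3 ± 3.39 (−7.65, 1.07, adjusted p = 0.00146) and miR-3548-y 0.217 ± 0.0209 (−7.78, 0.90, adjusted p = 0.000678). Without 1-month 2 these stood at −4.60, −4.01, −3.83, −5.62 and −6.57. chi-miR-130b-3p, a partner of proliferation, went from 88.3 ± 86.0 to 1.94 ± 0.612 (−5.50, 0.75, adjusted p = 0.00146, −4.34 without 1-month 2). chi-miR-15b-5p fell by 4.19 (0.63, adjusted p = 0.00192), miR-181-x by 3.93 (0.64, adjusted p = 0.00249), chi-miR-181b-5p by 3.35 (0.55, adjusted p = 0.00274) and chi-miR-16b-5p by 2.87 (0.52, adjusted p = 0.00446), with −3.09, −2.74, −2.45 and −2.01 without 1-month 2. chi-miR-92b, chi-miR-92a-3p and chi-miR-25-3p fell by 2.53 (adjusted p = 0.00777), 2.52 (0.00779) and 2.45 (0.00921), with −1.71, −1.69 and −1.58 without 1-month 2, and chi-miR-342-3p fell by 1.72 (0.00845). chi-miR-191-5p went from 50016 ± 33975 to 16194 ± 3258 (−1.63, 0.45, adjusted p = 0.026), with −0.93 (0.0171) without 1-month 2, and was lost without 24-month 3 (0.0886) or 5 (0.0533). Between 1 and 12 months it had stood at −1.38 (adjusted p = 0.0539), and passed without 1-month 1 or 3 or any 24-month library (0.0323 to 0.0355).

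The Hox miRNA chi-miR-196b went from 554 counts in the 1-month libraries to 3 in the 24-month libraries, a ratio of 157 (95% counting interval 53.3 to 762), with a fitted value of −6.96 (1.49, adjusted p = 0.00877). Without 1-month 2 the ratio was 111 (37.6 to 543). Without 24-month 2 the 24-month libraries held 0 counts, and the level was at least 100.02-fold lower at a floor of 3 counts over the group. Myeloid miR-223-y, chi-miR-223-5p and chi-miR-223-3p fell, with values of −6.03 (1.32, adjusted p = 0.00974), −6.03 (1.67, adjusted p = 0.0259) and −5.63 (1.48, adjusted p = 0.0219). Without 1-month 3 they stood at −3.47 (0.0479), −3.24 (0.146) and −2.58 (0.0784), and without 24-month 5 chi-miR-223-3p stood at −6.59. Without 24-month 5 miR-223-y held 422 counts against 2, a ratio of 120.4 (95% counting interval 33.1 to 998), and chi-miR-223-5p held 434 counts against 0, at least 82.6-fold lower at a floor of 3 counts over the group. Without 24-month 2 or 3, chi-miR-223-5p had an adjusted p of 0.0874 and 0.0923 and chi-miR-223-3p of 0.0893 and 0.103. Red cell chi-miR-144-3p went from 526 ± 275 to 150.5 ± 29.4 CPM (−1.81, 0.60, adjusted p = 0.0462), with −1.34 (0.123) without 1-month 2, and 0.0597 to 0.0974 without 1-month 1 or any 24-month library. chi-miR-16a-5p fell by 1.63 (0.55, adjusted p = 0.0487), with −0.69 (0.118) without 1-month 2, and 0.0528 to 0.149 without any 12-month or 24-month library. chi-miR-206 had a value of −2.76 (adjusted p = 0.152), and passed without 12-month 4 (−2.74, adjusted p = 0.00600).

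In total, edgeR called 246 of 937 miRNAs between 1 and 24 months, 82 higher and 164 lower: 106 goat-named, 109 with other names and 31 candidate entries without a family name. Of these, 243 changed at least 2-fold and 244 did not overlap, and over all tested 442 (47.2%) did not overlap, where chance gives 10%. Library size alone shifted the median of all miRNAs from −0.06 to −0.36 and gave 46 higher and 193 lower (19.2% higher, against 33.3%). The upper quartile gave 132 and 153 (46.3%), limma voom 117 and 140 (45.5%), no filter 65 and 223 (22.6%), and only the libraries of both ages 36 and 145 (19.9%). Without 1-month 2 the counts were 111 and 144, with 193 of the 246 kept, and without 24-month 2, 3 or 5 they were 158, 116 and 161.

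By camera, 5 of 19 lists passed between 1 and 24 months: miR-17-92 (adjusted p = 1.1e-10), leukocyte (3.0e-08), epithelial (1.0e-06), miR-29 and miR-21 (0.0143) and miR-30 (0.0219). None passed with an estimated correlation (adjusted p = 0.550, 0.365, 0.462, 0.365 and 0.365 with an estimated correlation). At least 5 lists passed camera in 8 of the 10 splits of these 6 libraries, the real one included. fry passed these 5 (0.0367, 0.00623, 0.0160, 0.00623 and 0.00623) and also gland, neural and Hox (0.0244 for each). miR-29 and miR-21 did not pass without 1-month 1 (0.0576). With only the more abundant arm miR-30 stood at 0.129, and with the first-base split as a covariate miR-29 and miR-21 stood at 0.0617.

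The 14 other lists did not pass camera between 1 and 24 months. Neural had a median of −1.27 (4 of 13 lower by both counts, adjusted p = 0.0582), Hox of −1.13 (1 of 5 lower by both counts, 0.160), miR-181 of −1.39 (1 of 4 lower, 2 adjusted over the list alone, 0.160), red cell of −1.44 (2 of 7 lower by both counts, 0.160) and miR-15/16 of −1.14 (6 of 16 lower, 7 adjusted over the list alone, 0.135). Picked after their values were seen, the further neural calls were chi-miR-129-5p (−5.01, adjusted p = 0.00367) and chi-miR-129-3p (79 counts at 1 month against 0 at 24 months, at least 22.3-fold lower at a floor of 3 counts over the group, adjusted p = 0.0104), and the further red cell call was miR-144-y (−1.49, adjusted p = 0.0461). let-7 had a median of 0.20 with 4 of 20 higher and 2 lower by both counts (0.389): chi-let-7a-5p, chi-let-7b-5p, chi-let-7a-3p (1.97, adjusted p = 0.0164) and chi-let-7b-3p (1.60, adjusted p = 0.0329) rose, and chi-let-7i-5p (−1.28, adjusted p = 0.0164) and chi-let-7d-3p (−1.44, adjusted p = 0.0329) fell, the last 4 picked after the fact. Gland stood at 0.14 with 2 of 8 higher, and 3 higher and 1 lower adjusted over the list alone (0.308), and hepatic at 3.16 with 0 of 3, and 2 higher adjusted over the list alone (0.306). Muscle had a median of −0.00 and a mean of 0.05 (2 of 9 higher by both counts, 0.458), DLK1-DIO3 a median of 0.06 (1 of 84 higher, 0 adjusted over the list alone, 0.283), growth network of 0.49 (1 of 20 lower, 0 adjusted over the list alone, 0.283), endothelial of 0.24 (1 of 4 higher, 0 adjusted over the list alone, 0.442), mesenchymal of 0.13 (1 of 15 higher by both counts, 0.442) and the miR-34 family of −0.29 (0 of 6, 0.762). The single calls picked after the fact were chi-miR-656 (1.398, adjusted p = 0.0431, and 0.0622 without 1-month 2), chi-miR-335-3p (−1.66, adjusted p = 0.0275) and miR-145-y (2.10, adjusted p = 0.0157), and chi-miR-499-3p rose in muscle (1.46, adjusted p = 0.0289). Library size alone turned the medians of let-7, DLK1-DIO3, gland, endothelial and mesenchymal to −0.05, −0.26, −0.11, −0.07 and −0.22, and the upper quartile turned that of muscle to 0.10. Neural passed without 1-month 2 (−0.46 at 0.0326, adjusted p = 0.379 with an estimated correlation), 1-month 3 (−1.19 at 0.0348, 0.579) or 24-month 3 (−1.69 at 0.0359, 0.518), DLK1-DIO3 (0.27 at 0.0240, 0.643), miR-15/16 (−1.41 at 0.0348, 0.579) and miR-181 (−1.75 at 0.0348, 0.579) without 1-month 3, and hepatic without 24-month 5 (3.53 at 0.0258, 0.549). Without 1-month 2 the miR-15/16 and miR-181 medians shrank to −0.38 (0.111) and −0.35 (0.339), and the DLK1-DIO3 median was −0.29 with 2 members higher and 3 lower and the mesenchymal median −0.40 with 4 higher and 6 lower, with a camera direction of down for both. With the first-base split as a covariate and all libraries DLK1-DIO3 passed upward (0.28 at 0.0209, with 9 members higher and 0 lower).

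Over the 3 ages together, 192 miRNAs differed. In 46 both older ages lay above 1 month, in 146 both lay below, and in 0 they lay on opposite sides. The comparisons of 12 and of 24 months with 1 month shared 169 calls, 49 higher and 120 lower, and their log2 fold changes correlated at 0.903. Both comparisons use the same 1-month libraries, which alone gives a correlation: 50 simulations without any age effect had a mean of 0.494 and a maximum of 0.603. The covariance was 3.36, against a simulated mean of 0.277 and maximum of 0.399, and the same sign was seen in 88.9% of miRNAs, against a simulated 66.3%. Independent lists of these sizes would share 4.90 higher and 21.7 lower, a figure that leaves out the effect of the shared 1-month libraries. The simulations gave each miRNA the same spread at every age. In the data the shared 1-month libraries varied more, with within-age correlations from 0.915, against 0.969 at 12 months and 0.974 at 24 months. Noisier shared libraries would raise the simulated values, so these are too low as a baseline and do not size the excess. Part of the excess also stays open, since 3 controls cannot be split into separate sets for each comparison.

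**Figure D3:**
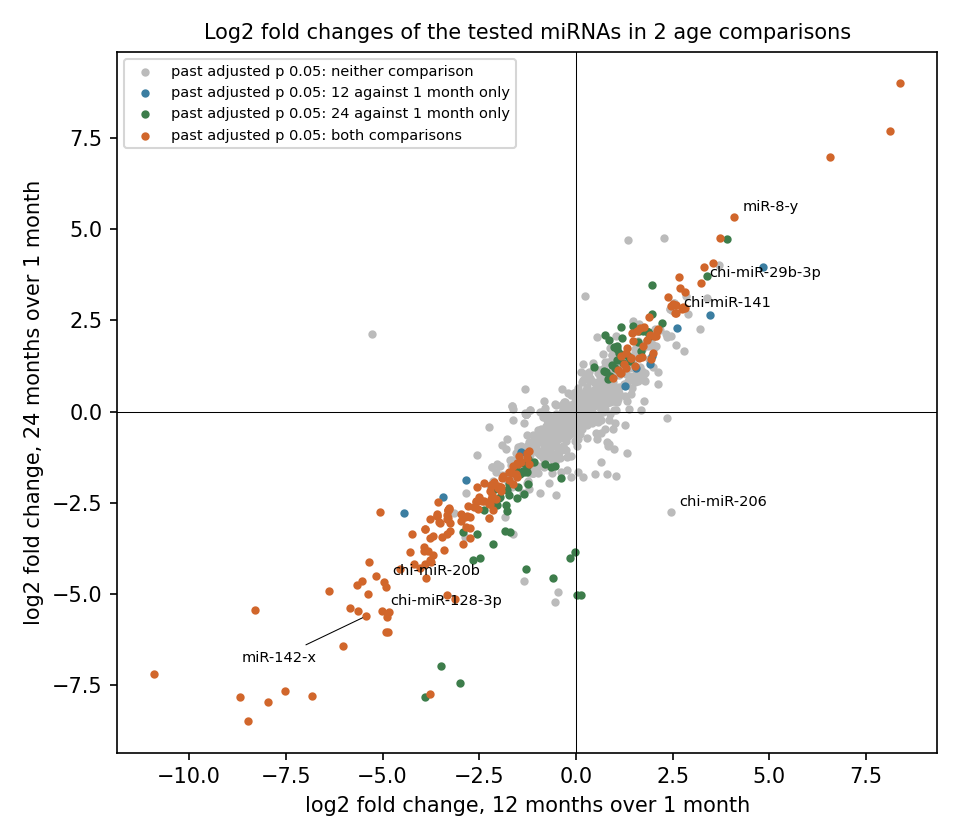
Log2 fold changes of 937 miRNAs at 12 months (x axis) and 24 months (y axis), both against 1 month. Points are miRNAs coloured by the comparison in which they passed, and they lie near the diagonal with a correlation of 0.903.

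The libraries also part by a ratio that the labels do not name. The share of miR-26-x over chi-miR-26a-5p, entries that differ in their first base, was 1.10% to 1.30% in 1-month 2, 12-month 4 and 24-month 3 and 5, and 0.554% to 0.614% in the other 5 libraries. With this split as a covariate edgeR called 249 miRNAs between 1 and 12 months (178 of the 180 kept), 0 between 12 and 24 months (44 at an unadjusted p under 0.05) and 343 between 1 and 24 months (240 of the 246 kept). Some names moved with the split: in older libraries miR-8-y stood at 121, 169 and 166 CPM on its high side and at 12.0, 14.3 and 11.4 on its low side, and miR-236-y at 13.4, 11.4 and 16.8 against 2.19, 1.71 and 2.22.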

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

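Over 282 named values, 8721 comparisons with an alternative setting left 7778 with the same call and direction, while 255 lost a call, 231 gained 1, 454 without a call changed sign and 3 turned around, under 25 settings fixed before the data were examined and 13 added after they had been seen. The added settings named here are goat-named entries only, the first-base split and the removal of 1-month library 2 with 12-month library 4. The 3 turns were all chi-miR-206 between 1 and 12 months, at 2.45 without a call over all libraries and 2.66 without 1-month 1, and at −2.30 (adjusted p = 0.036) without 12-month 4, −2.12 (0.0162) in the low first-base libraries and −2.17 (0.0207) without 1-month 2 and 12-month 4, where its adjusted p over 31 alternatives ran from 0.0162 to 0.965. Construction explains these turns, since 12-month 4 holds most of the chi-miR-206 counts of its age.

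The count of 180 miRNAs between 1 and 12 months was 285 with DESeq2, 99 with goat-named entries only, which hold fewer tests, and 83 without 12-month 4, with up to 218 on leaving out another library, 1-month 2. The count of 0 between 12 and 24 months in edgeR, with 40 at an unadjusted p under 0.05 and 0 by DESeq2 and limma voom, was 2 without 12-month 5 and 5 with no filter: miR-122-y higher, and miR-731-y, miR-10225-y, miR-741-y and miR-743-y lower, each with at most 141 counts in the larger age and all picked after the fact. The count of 246 between 1 and 24 months was 146 with a mean of at least 10 CPM, 125 with goat-named entries only, and 158, 116 and 161 without 24-month 2, 3 or 5. The 192 miRNAs with any difference were 303 with no filter, 127 with a mean of at least 10 CPM, 299 with DESeq2 and 109 with goat-named entries only. Filters and name classes change how many entries are tested, and for the other shifts the cause was not tested.

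With the replicate number as a block, the counts were 4 between 1 and 12 months, 71 between 1 and 24 months and 13 for any difference, and 0 lists passed between 12 and 24 months. By camera against 1 month, miR-29 and miR-21 lost its call at 12 months (0.43 at an adjusted p of 0.148) and 24 months (1.63 at 0.0764). Calls were gained by DLK1-DIO3 (0.0244), neural (0.0450) and miR-15/16 (0.0450) at 12 months, and by growth network (0.0436) and neural (0.0167) at 24 months. The replicate numbers do not pair the goats, since each library came from a separate animal. Number 1 occurs only in 1-month 1 and number 4 only in 12-month 4, so the block fits these libraries exactly and spends residual degrees of freedom. The 5 pairs of libraries with the same number had correlations of −0.212 to 0.178, against up to 0.285 for other pairs (1-month 2 with 12-month 4). So few pairs cannot show whether a shared source exists.

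The lists past camera were 4, 3 and 5 in the 3 comparisons, and 0, 0 and 0 with an estimated correlation. Between 12 and 24 months they were 0 by fry, and 1 without 12-month 3, without 24-month 2, or without 1-month 2 and 12-month 4 together. By fry 8 passed between 1 and 24 months, and without 1-month 3 the count was 9 between 1 and 12 months and 9 between 1 and 24 months. For the list counts the cause was not tested. TMM with each of the 8 other reference libraries gave 178 to 197 calls between 1 and 12 months, with 12.7% to 33.3% higher, and 242 to 288 between 1 and 24 months, with 24.7% to 42.0% higher. The pseudocount alternatives do not apply to counts.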

Other observations

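The tests in this part on 1-month library 2, on the first-base split and on the miR-29 family were chosen after the results were seen, as were the thymocyte, mature lymphocyte and myeloid, and fish-named lists. The mixture tests of the miRNAs higher and lower at 1 month and the counts over splits were written before their own outcomes. The mixture tests take library 2 as their source and miRNAs called without it, so they already build on library 2 standing apart. The thymocyte list took 9.17 ± 8.16% of counts at 1 month, with 18.5% in library 2 (95% interval 18.52 to 18.56%) against 5.29% and 3.68% in libraries 1 and 3, and 0.603% and 0.493% at 12 and 24 months. The mature lymphocyte and myeloid list took 0.667%, 0.180% and 0.141% at the 3 ages (exact two-sided p = 0.1 for each older age against 1 month, the smallest for 3 against 3), and held 0.690% in library 2 against 0.423% and 0.888% in libraries 1 and 3. Lymphocyte chi-miR-150 and chi-miR-155-5p, picked after their values were seen, fell by 3.93 (adjusted p = 0.0011) and by 3.47 (adjusted p = 0.00233) between 1 and 12 months, the latter by 2.84 without 1-month 2. Of the miR-17-92 paralogs also picked so, chi-miR-17-5p fell by 3.25 and chi-miR-106a-5p by 4.20, with −2.43 and −3.33 without 1-month 2.

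Single libraries also held high levels of some tissue miRNAs. In 12-month 4 the muscle miRNAs stood at 869 unscaled CPM of chi-miR-206, against 9.89 and 9.37 in 12-month 3 and 5, with 855 of chi-miR-1, 309 of chi-miR-133a-3p and 46.1 of chi-miR-133b. chi-miR-499-5p, of the same list, stood at 86.3 TMM-scaled CPM there against 64.5 and 83.0, and the muscle list took 0.246% of counts (95% interval 0.243 to 0.249%). In 24-month 3 liver chi-miR-122 stood at 1443.6 CPM and the hepatic list took 0.142% (95% interval 0.139 to 0.144%). Entries with names known from fish held 1014, 5445 and 786 counts in the 1-month libraries, 414, 2478 and 168 at 12 months and 144, 88 and 115 at 24 months, a mean of 0.0192%, 0.0114% and 0.00115% of counts. The folds of the 4 muscle miRNAs in 12-month 4 over the higher of 12-month 3 and 5 had a lowest value of 6.34, and tests run on the muscle and fish-named values are not weighed here, where 3 patterns are. Red cell miRNAs took 0.2997 ± 0.1008%, 0.217 ± 0.143% and 0.109 ± 0.00743%, miR-30 took 3.65%, 4.84% and 4.95%, and miR-29 and miR-21 took 1.60%, 1.37% and 1.29%. Shares of the remaining lists at 1, 12 and 24 months were 0.416%, 0.461% and 0.444% for DLK1-DIO3, 0.158%, 0.202% and 0.218% for growth network, 0.649%, 0.350% and 0.355% for Hox, and 0.00449%, 0.00527% and 0.00272% for the miR-34 family.

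Library 2 of the 1-month goats stood apart from libraries 1 and 3. An exchange with an older library is argued against, since the highest leukocyte share of any older library was 0.691% and the lowest at 1 month 3.70%. For the leukocyte share alone the first-base split is argued against. Older libraries on its high side held 0.788 times the leukocyte share of those on its low side. Over all tested miRNAs, deviations from the age means in library 2 correlated at 0.285, 0.151 and 0.0417 with 12-month 4, 24-month 3 and 24-month 5, all on the high side. With low-side 12-month 3, 12-month 5 and 24-month 2 they correlated at −0.138, −0.205 and −0.159. A part of the split in other miRNAs of library 2 therefore stays open. Lymphoid tissue of a thymus type taken with the gland stays an open candidate explanation: the thymocyte list was 3.05-fold higher in library 2 at its median and the mature lymphocyte and myeloid list 0.999-fold, but both lists were put together after the levels had been seen, so this decides nothing, and chi-miR-155-5p of the latter list stood at 1394 CPM against 432 and 584. Of the 14 thymocyte entries 6 are also in the miR-17-92 list and 9 stood over 10 CPM in every older gland, all 5 of the other list are leukocyte members and 4 of them stood over 10 CPM in every older gland, and no sort or gate that would remove such cells is given. Of 231 abundant miRNAs, 6 were at least 4-fold higher and 41 at least 4-fold lower in library 2, and a glandular state of that goat itself was not tested.

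The many miRNAs that parted the 1-month goats from the older ones may rest in part on a share of whatever tissue fills library 2 in libraries 1 and 3. At mixing shares of 50% and 34%, chosen to explain the most miRNAs and so in favour of this explanation, 65.1% of those higher at 1 month (69 of 106) and 61.3% of those lower (46 of 75) lay within 2-fold of the mixture in both libraries. Of the 106 and 75, 17 and 4 lay beyond library 2 itself. Without a mixture 0% and 21.3% lay within 2-fold of the older mean in both libraries, a share that the choice of called miRNAs itself holds down. No mixture with another library was tried, so these shares leave the explanation possible and no more. For the miR-29 family the test was undecided by its own rule: the mixture held from 1.54 to 4.62 times the measured level over 5 entries and both libraries, so neither all within 2-fold nor all beyond it. The median was 3.03, and chi-miR-29b-3p stood at 70.7 and 86.5 unscaled CPM against 313 and 399.5 for the mixture. Every value of the mixture lay above the measured one. The shares were chosen over all the called miRNAs, and library 2 itself held chi-miR-29b-3p at only 44.1 unscaled CPM, so a larger share would come nearer. The entries are also not independent, since miR-29-y is a longer form of chi-miR-29a-3p. The test therefore does not decide whether a mixture is the source of the low miR-29 levels. A second form of the test, 0% of the 5 within 2-fold in both libraries, was written after the first had come out undecided and is not weighed. The age of the goats, which the design names, stays open and untested as the source of these differences. Of 100 of the 280 splits of all 9 libraries into 3 groups, the real one included, 3 gave at least the 192 miRNAs with any difference. That is a share under 0.05, which makes chance an unlikely source but does not exclude it. The highest other split, with 203, also kept the 1-month libraries together and mixed the older ages. So the count shows only that the 1-month libraries stand apart. It does not bear on the source of that, or on a difference between 12 and 24 months.

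For pairs of ages the 10 splits of 6 libraries are too few for a share under 0.05. Between 1 and 12 months the real split gave 180 miRNAs and the highest other 0 (1 of 10 splits as large), between 12 and 24 months 0 by edgeR and 1 (10 of 10, with 40 miRNAs at an unadjusted p under 0.05 and 0 calls by DESeq2 and limma voom), and between 1 and 24 months 246 and 0 (1 of 10). For lists the real split and the highest other gave 4 and 11 (10 of 10 splits as large), 3 and 6 (6 of 10), and 5 and 9 (8 of 10). The number of lists past camera therefore does not set the real ages apart from mixed ones.

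The libraries part by a first-base ratio in a way the labels do not name. A library or sequencing batch fits, since the median over 7 further entries that differ from a goat miRNA in their first base put 9 of 9 libraries on the same side. Taken singly, 5 of them part the sides fully, where chance gives 0.794% for each, while miR-411-y and miR-1-z do not. Age of the goats is argued against as its source, since 3 of 3 ages have libraries on both sides. The split could move single names such as miR-8-y, but with it as a covariate 249 and 343 miRNAs were called against 1 month, including 178 of the 180 and 240 of the 246 called without it.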
